A study of Rattus norvegicus with 3 samples.

How the data were processed

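Single-cell transcriptomes of rat femoral defect tissue were measured with droplet-based 3' chemistry in 3 libraries, 1 each for the graphite, fullerene and diamond scaffold, 1 month after implantation. Per the file headers and the submitters' processing notes, the deposited matrices hold integer UMI counts per gene and barcode from Cell Ranger 7.1.0, restricted to barcodes called as cells, with no normalization. The genome build and annotation are not given in the sources used here. Each matrix held 25399 genes, of which 7254 had no symbol. Each library was also given as a copy with the same entries, and that copy was not used here.

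Cells were kept with at least 500 detected genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes. Scrublet, as implemented in scanpy 1.11.5, was run per library. Its automatic threshold marked 1 cell in GP, 1 in FL and 0 in DM, too few to have worked, so the highest-scoring cells were removed at a rate of 0.8% per 1000 cells, or 492, 343 and 432 cells. The filters had left 7846, 6548 and 7350 cells. Kept cells of all libraries were clustered together without integration on log-normalised counts, 2000 variable genes (mitochondrial, ribosomal, haemoglobin and immunoglobulin genes left out), 30 principal components, 15 neighbours and the Leiden method at a resolution of 1 (igraph 0.11.9), which gave 24 clusters. Clusters were named from 312 marker genes of 29 cell types, 301 of them found, and names stand as X-like because they rest on markers alone. Mesenchymal cells were clustered again on their own, since the class had at least 100 cells in each library.

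With 1 library per scaffold no test, p-value or standard error was computed, and cells were not treated as replicates. Shares carry exact Clopper-Pearson intervals and levels in counts per 1000000 UMIs of a class (CPM) exact Poisson intervals. Ratios between libraries, after division by the UMIs of the class, carry exact conditional binomial intervals. All cover counting error only, at 95%. A class was compared where both libraries held at least 20 of its cells and 20000 UMIs, and a gene where it had at least 50 UMIs over the pair. Where a library had 0 UMIs of a gene, the ratio is a lower bound set at 3 UMIs in that library. The marker genes, 33 gene lists, filters, comparisons and the rule for named genes were fixed before the data were examined. 552 of 568 list members were found, 4 names of lists and markers through synonyms in the gene table supplied with the reference. Lists were described by members at least 1.5-fold higher or lower, the median log2 ratio and its percentile among the medians of 10000 random lists of equal size matched over 20 expression bins. A median lies outside the range of random lists below percentile 2.5 or above 97.5. The percentile is the share in percent of random medians below the observed one, with ties split evenly, and describes these libraries alone.

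Under the rule for named genes, genes were ranked by the interval bound nearest to 1, and the first 5 higher in each library were named for each pair in the mesenchymal class and the first 3 in the mono-macrophage, neutrophil and endothelial classes. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and Y-linked genes and genes without a symbol stayed out of the ranking. Up to 4 members of each list, those with the bound farthest from 1, and a fixed set of bone, vessel and myeloid genes could be named as well, each with its ratio in all cells outside the class. Known ratios and planted lists were simulated at the mesenchymal and mono-macrophage library sizes. They tested intervals and percentiles for counting error alone.

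Alternatives were looser and stricter cell filters, no removal of doublets, other Leiden resolutions, 4000 variable genes, each library clustered alone, median of ratios scaling, equal weight for each cell, thinning of each cell to 2000 UMIs, list minimums of 10 and 200 UMIs and totals without free RNA genes. Settings added after the data were seen took single clusters of a class, left out subclusters led by genes of other classes, left out the top cell of each gene, or changed the denominator of the shares. Gene comparisons left out erythroid cell-like, mast cell or basophil-like, dendritic cell-like and progenitor-like classes and osteoclasts, whose markers no cluster met. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.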

Results

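Single-cell RNA sequencing was performed on rat bone tissue taken from a femoral defect 1 month after it had been filled with an artificial scaffold. The 3 scaffolds shared the idea of a carbon crystal lattice and differed in architecture, which followed graphite (GP), fullerene (FL) or diamond (DM). Each scaffold was represented by 1 library of droplet-barcoded cells, the number of animals behind a library was not stated, and no unimplanted or empty-defect library was part of the design. The GP matrix held 9580 cell barcodes and 51923239 unique molecular identifiers (UMIs), the FL matrix 8214 barcodes and 56818851 UMIs, and the DM matrix 9488 barcodes and 57228511 UMIs. After filtering and removal of likely doublets, 7354 cells remained in GP, 6205 in FL and 6918 in DM, with a median of 3742, 4843 and 3936 UMIs per cell. With 1 library per scaffold no test between scaffolds was possible, and every difference below lacks a replicate. Intervals are at 95% and cover counting error only. The series title names osteogenic progression as its theme, so the comparisons among the 3 scaffolds centre on the bone-forming cells, followed by the myeloid and endothelial cells around them.

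The libraries differed in which cells they held. Mesenchymal cells, the class of stromal-like, chondrocyte-like and pericyte-like clusters from which bone and cartilage form, made up 2.37% (2.03 to 2.74) in GP, 25.3% (24.2 to 26.4) in FL and 13.4% (12.6 to 14.2) in DM. B-lineage cells of the marrow went the other way, with 70.5% (69.4 to 71.5) in GP, 41.3% (40.0 to 42.5) in FL and 61.2% (60.1 to 62.4) in DM. Endothelial-like cells, which line vessels, made up 0.598% (0.435 to 0.802) in GP, 2.18% (1.83 to 2.57) in FL and 3.04% (2.64 to 3.47) in DM. Monocyte-like and macrophage-like cells together held 4.98% (4.49 to 5.50) in GP, 8.38% (7.70 to 9.10) in FL and 5.71% (5.17 to 6.28) in DM, and neutrophil-like cells 7.91% (7.31 to 8.55) in GP, 9.11% (8.40 to 9.85) in FL and 5.06% (4.55 to 5.60) in DM. T cell-like and NK cell-like cells had nearly equal shares of 6.92% (6.35 to 7.53) in GP, 6.96% (6.34 to 7.62) in FL and 7.01% (6.42 to 7.64) in DM. Mast cell or basophil-like cells held 1.35% (1.10 to 1.64) in GP, 0.677% (0.488 to 0.914) in FL and 0.448% (0.305 to 0.635) in DM. Dendritic cell-like cells held 1.39% (1.13 to 1.68) in GP, 1.34% (1.07 to 1.66) in FL and 0.997% (0.777 to 1.26) in DM, and granulocyte-monocyte progenitor-like cells 0.979% (0.767 to 1.23) in GP, 1.64% (1.34 to 1.99) in FL and 0.968% (0.751 to 1.23) in DM. Cluster 19, which stayed without a name, held 0.694% (0.517 to 0.911) in GP, 1.05% (0.809 to 1.33) in FL and 0.607% (0.438 to 0.820) in DM, and the erythroid cell-like cluster 17, which also carried mast cell and eosinophil genes, was not compared. Counted among cells outside the B-lineage alone, a denominator chosen after the data were seen, the mesenchymal share was 8.02% (6.91 to 9.25) in GP, 43.0% (41.4 to 44.6) in FL and 34.6% (32.8 to 36.4) in DM, so its order among the libraries stayed. On that basis T cell-like and NK cell-like cells held 23.5% in GP, 11.9% in FL and 18.1% in DM, neutrophil-like cells 26.8% in GP, 15.5% in FL and 13.1% in DM and the mono-macrophage class 16.9% in GP, 14.3% in FL and 14.7% in DM. Dendritic cell-like cells held 4.70% in GP, 2.28% in FL and 2.57% in DM and progenitor-like cells 3.32% in GP, 2.80% in FL and 2.498% in DM, so their order turned. No cluster met the osteocyte markers, although the labels give osteocytes as the cell type. Median depth differed between classes as well as libraries, from 2769 UMIs in mast cell or basophil-like cells of GP to 16484 in progenitor-like cells of GP, and a share can shift with the depth at which a barcode was called a cell.

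**Figure D1:**
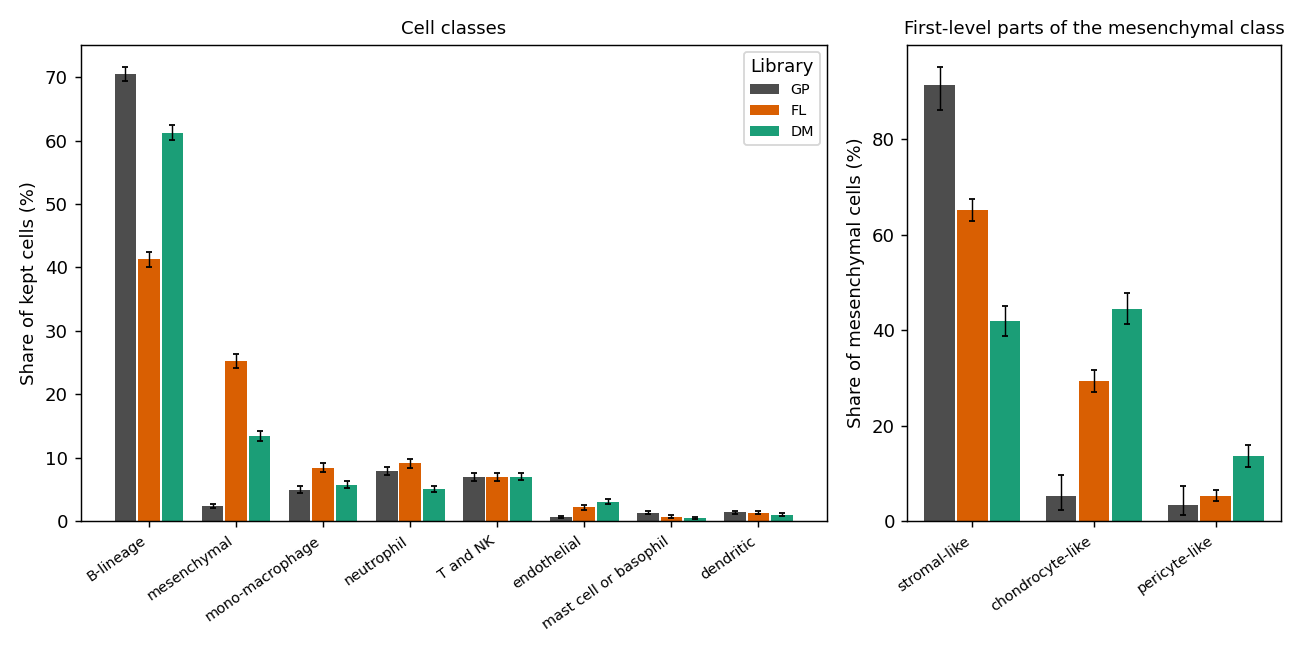
Share of cells in percent (vertical axis) per cell class (left) and share of mesenchymal cells per mesenchymal cluster (right) in the 3 libraries, with bars for the share and whiskers for the exact 95% binomial interval. The mesenchymal class ranges from 2.37% in GP to 25.3% in FL, and the chondrocyte-like part of it from 5.17% in GP to 44.5% in DM.

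Within the mesenchymal class, chondrocyte-like cells were close to missing in GP. The chondrocyte-like cluster 22 held 9 of 174 mesenchymal cells in GP, 461 of 1568 in FL and 413 of 928 in DM, or 5.17% (2.39 to 9.59) in GP, 29.4% (27.2 to 31.7) in FL and 44.5% (41.3 to 47.8) in DM. Stromal cell-like cells of cluster 12 made up 91.4% (86.2 to 95.1) in GP, 65.2% (62.8 to 67.6) in FL and 41.9% (38.7 to 45.2) in DM, and pericyte or smooth muscle cell-like cells of cluster 24 3.45% (1.28 to 7.35) in GP, 5.36% (4.30 to 6.59) in FL and 13.6% (11.4 to 16.0) in DM. When the class was clustered again alone, chondrocyte-like subclusters held 2.30% (0.630 to 5.78) in GP, 27.2% (25.0 to 29.4) in FL and 33.0% (29.95 to 36.1) in DM. Stromal cell-like ones held 14.9% in GP, 21.2% in FL and 6.68% in DM. An osteoblast-like subcluster had 1 cell in GP, 18 in FL and 0 of 928 in DM, where 0 cells allow a share of up to 0.323%. It held 5, 34 and 2 cells with the looser filter. With no doublets removed it held 11, 24 and 11, led also by stromal Lepr and Cxcl12. Another 24, 137 and 42 cells without leading Bglap took its name, so its near absence in GP and DM stays open. Fibroblast-like cells numbered 8 in GP, 34 in FL and 0 in DM. Resolution 0.5 named a further 67, 601 and 165. Subclusters without a name held 74.1% (67.0 to 80.5) in GP, 43.4% (40.9 to 45.9) in FL and 46.9% (43.6 to 50.1) in DM. Of these, subclusters 5, 10 and 15 had some leading genes of another class. They held 39.1% (31.8 to 46.8) in GP, 15.4% (13.6 to 17.3) in FL and 18.3% (15.9 to 21.0) in DM. Subcluster 5 (Gzmb, Areg, proteases), nearest to stromal cells, held 31.6% (24.8 to 39.1) in GP. Osteoblast-like and fibroblast-like subclusters of the main setting come mostly from FL and cannot be separated from it, so no class was built on them. Cluster 12 holds most mesenchymal cells of GP and cluster 22 the largest part in DM. Values over the class stand beside those in cluster 12 (stromal-like) alone, chosen after the data were seen.

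Free RNA of collagen genes followed the same order as the mesenchymal share. Col1a1, the main collagen of bone, stood at 61.2 counts per 1000000 UMIs (CPM) in B-lineage cells of GP, 626 in FL and 549 in DM, although B cells do not make it. Col2a1, the main collagen of cartilage, stood at 0.260, 73.0 and 48.1 there. Over all barcodes of a library, removed ones included, Col2a1 reached 5.60 CPM in GP, 1343 in FL and 856 in DM. Each ratio inside a class therefore stands beside the one outside it, and a match may be free RNA of the class or a shared change. In the gene lists, a member counted as higher where its ratio was at least 1.5. Medians are log2 ratios of the first library over the second in the order GP, FL, DM, and percentiles place a median among those of 10000 random lists matched on expression. Single-gene ratios stand with their interval and the ratio outside the class.

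The first comparison set graphite against fullerene architecture in mesenchymal cells. By their medians, cartilage genes, glycolysis and hypoxia genes and mineral-binding matrix genes were lower in GP than in FL, and matrix proteases and niche factors were higher in GP. The first 3 differences were smaller in stromal-like cells alone, where cartilage and glycolysis genes stayed lower in GP and the mineralisation median came near 0. In the chondrogenic list 18 of 18 members were higher in FL and 0 in GP (median -5.19, percentile 0, -1.36 stromal-like alone). The genes ranked highest in FL were Col2a1 (8909-fold, 1599 to 351908, outside 253), Snorc (3499-fold, 628 to 138210, outside 36.2), Clec3a (at least 699.8-fold, outside at least 115), Col9a1 (at least 395-fold, outside 202 with interval 68.7 to 985) and Col10a1 (at least 352-fold, outside 37.8). All 5 are cartilage matrix genes, Col10a1 being the collagen of hypertrophic cartilage. Col2a1 and Snorc each rested on 1 UMI in GP, where 1 barcode removed as a doublet held 277 of the 291 Col2a1 UMIs of the library. With no doublets removed the ratios were 35.2 and 10.6, so their direction stayed but not their size. The genes ranked highest in GP were Ostn (219.6-fold, 58.1 to 1856, 2 and 2 UMIs outside), C1qc (11.01-fold, 6.92 to 17.7, outside 0.0795) and Ap5b1 (9.09-fold, 6.14 to 13.5, outside 0.974), then Pla2g2a (9.53-fold, 5.79 to 15.8, outside 0.881) and Cd2 (8.48-fold, 4.77 to 15.2, outside 0.763). Ostn encodes a secreted bone peptide, C1qc a complement subunit of macrophages and Cd2 a T cell surface protein. A single cell held over 50% of the UMIs in GP for Ostn, C1qc, Ap5b1, Pla2g2a and Cd2.

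Among glycolysis and hypoxia genes 15 of 23 members were higher in FL and 0 in GP (median -0.86, percentile 0, -0.35 stromal-like alone). Egln3 (28.6-fold, 13.1 to 78.0, outside 1.86), Bnip3 (5.55-fold, 4.79 to 6.47, outside 1.79) and Car9 (9.33-fold, 4.70 to 21.7, outside 1.91) led it in FL, a prolyl hydroxylase, a mitophagy receptor and a carbonic anhydrase that all respond to low oxygen. In the osteoblast maturation list 8 of 17 members were higher in FL and 1 in GP (median -0.45, percentile 0.01, -0.09 stromal-like alone). Spp1, which encodes osteopontin, was 7.19-fold higher in FL and Smpd3, a sphingomyelinase needed for mineral deposition, 7.17-fold, with ratios outside the class of 3.44 and 1.45. The mineralisation list, which shares Spp1, Ibsp, Bglap and Dmp1 with it, gave a median of -0.84 over the class and -0.08 in stromal-like cells alone. For fibrillar collagen and matrix genes 5 of 31 members were higher in FL and 1 in GP (median -0.14, percentile 0.49, -0.25 stromal-like alone). Leading it were Col11a1 (3.87-fold, 3.70 to 4.05, outside 25.1) and Fn1 (2.40-fold, 2.34 to 2.46, outside 2.78). For matrix proteases and their inhibitors 4 of 18 members were higher in GP and 0 in FL (median 0.31, percentile 99.7, 0.12 stromal-like alone, 0.27 without subclusters 5, 10 and 15). Plat (2.58-fold, 2.33 to 2.85, outside 0.264) and Mmp3 (1.90-fold, 1.79 to 2.01, outside 0.231), a plasminogen activator and a stromelysin, led it in GP. For haematopoietic niche factors 4 of 13 members were higher in GP and 0 in FL (median 0.37, percentile 99.6, 0.00 stromal-like alone). Examples were Vcam1 (2.19-fold, 1.97 to 2.43, outside 0.612) and Il7 (2.38-fold, 1.92 to 2.93, outside 0.505), an adhesion molecule and a lymphocyte growth factor. For osteoclast coupling signals 3 of 12 members were higher in GP and 2 in FL (median 0.26, percentile 98.0, -0.13 stromal-like alone). Higher in FL within it were Il11 (20.9-fold, 9.55 to 57.0, outside 4.57) and Tnfrsf11b (7.98-fold, 6.18 to 10.48, outside 191 with interval 33.7 to 7599), a cytokine and the decoy receptor that restrains osteoclasts. For adipogenic genes 3 of 8 members were higher in GP and 2 in FL (median 0.29, percentile 97.9, 0.17 stromal-like alone). For haemoglobin genes, a sign of red-cell RNA, 3 of 3 members were higher in FL and 0 in GP (median -2.26, percentile 0.065).

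The other 14 of 24 lists had medians within the 95% range of random lists between GP and FL. The calcium channel Trpv4 (12.3-fold, 5.92 to 30.6, outside 4.61), which senses mechanical load, the growth factors Bmp6 (10.8-fold, 8.35 to 14.1, outside 2.65) and Bmp2 (2.01-fold, 1.81 to 2.24, outside 2.30), the cyclin Ccnd1 (6.59-fold, 4.98 to 8.90, outside 3.51) and the ectoenzyme Nt5e (4.96-fold, 3.56 to 7.11, outside 1.16) were higher in FL. The actomyosin and SRF target list had a median of 0.14 over the class and -0.30 in stromal-like cells alone (percentile 0.135). The GP values rest on 174 mesenchymal cells. Under other settings the direction turned for osteoblast maturation genes (0.050), osteoclast coupling signals (-0.18), Bglap, Mepe and Bmp2 with cells thinned to 1 depth, fibrillar collagen and matrix genes (0.0017), Bglap, Il7 and Mmp3 without subclusters 5, 10 and 15, Ibsp, Postn, Bmp2 and Trpv4 in stromal-like cells alone, Bglap with the looser cell filter and Bglap and Mepe with no doublets removed. It turned as well for Bglap with each cell weighted alike, C1qc, Ap5b1 and Cd2 with the stricter cell filter, C1qc without subclusters 10 and 15 and C1qc and Ap5b1 without the top cell of each gene.

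Graphite set against diamond architecture gave a similar picture for cartilage and glycolysis genes, with lower medians of cell cycle genes in GP and higher ones of protease, YAP and TAZ target and immediate early genes. In the chondrogenic list 18 of 18 members were higher in DM and 0 in GP (median -4.74, percentile 0, -0.69 stromal-like alone). The genes ranked highest in DM were Col2a1 (8264-fold, 1483 to 326419, outside 185), Snorc (1848-fold, 332 to 73012, outside 19.1) and Clec3a (at least 362-fold, outside at least 63.8), then Col9a1 (at least 177-fold, outside 94.7 with interval 32.0 to 463) and Col11a2 (259-fold, 111 to 799, outside 12.0), again cartilage genes. With no doublets removed Col2a1 was 31.1-fold and Snorc 5.60-fold higher. Ranked highest in GP were Ostn (324-fold, 55.9 to 13024, 2 and 0 UMIs outside), Bglap (32.4-fold, 27.8 to 38.1, outside 0.589) and Igfbp2 (39.1-fold, 17.6 to 102, 1 and 1 UMIs outside), then Ap5b1 (14.0-fold, 8.57 to 23.5, outside 0.836) and C1qc (14.9-fold, 8.51 to 27.2, outside 0.168). A single cell held over 50% of the GP UMIs for Ostn, Bglap, Igfbp2, Ap5b1 and C1qc. For Bglap, which encodes osteocalcin, that cell held 97.1%, and the ratio was 1.06 without the top cells and 1.26 with no doublets removed. Among glycolysis and hypoxia genes 13 of 23 members were higher in DM and 1 in GP (median -0.84, percentile 0, -0.32 stromal-like alone). Egln3 (14.3-fold, 6.51 to 39.1, outside 0.823) and Bnip3 (4.19-fold, 3.61 to 4.89, outside 0.978) were higher in DM.

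For mineralisation genes between GP and DM 10 of 15 members were higher in DM and 4 in GP (median -1.23, percentile 0, 0.01 stromal-like alone). Leading it were Spp1 (14.6-fold, 13.9 to 15.4, outside 4.66) and Dmp1 (19.5-fold, 8.29 to 60.2, outside 7.24), a matrix phosphoprotein pair of mineralising bone. In the osteoblast maturation list 6 of 17 members were higher in DM and 4 in GP (median -0.28, percentile 2.10, 0.28 stromal-like alone), so its direction was opposite in stromal-like cells. For matrix proteases and inhibitors 7 of 18 members were higher in GP and 0 in DM (median 0.35, percentile 99.7, 0.08 stromal-like alone, 0.32 without subclusters 5, 10 and 15). Leading it were Plat (2.07-fold, 1.87 to 2.29, outside 0.183) and Plau (2.08-fold, 1.76 to 2.46, outside 0.235), both plasminogen activators. For YAP and TAZ target genes 6 of 21 members were higher in GP and 3 in DM (median 0.39, percentile 100, 0.18 stromal-like alone). Higher in GP stood Igfbp3 (2.41-fold, 2.24 to 2.61, outside 0.162) and Nuak2 (2.79-fold, 1.88 to 4.09, outside 0.985), and in DM Nt5e (6.79-fold, 4.88 to 9.73, outside 0.901). For the WNT pathway 7 of 22 members were higher in GP and 6 in DM (median 0.25, percentile 99.1, -0.05 stromal-like alone). For immediate early and dissociation genes 7 of 20 members were higher in GP and 0 in DM (median 0.43, percentile 99.9, 0.07 stromal-like alone). For cell cycle genes 14 of 27 members were higher in DM and 0 in GP (median -0.67, percentile 0, 0.12 stromal-like alone). For MHC class II genes 5 of 5 members were higher in DM and 0 in GP (median -1.44, percentile 0.115, -0.26 without subclusters 10 and 15), so most of this difference lay in subclusters led by genes of blood cells. Foreign body and fibrosis genes had a median of -0.21 (percentile 2.22, -0.15 in stromal-like cells alone), and nuclear genes of oxidative phosphorylation one of -0.17 (percentile 2.06, -0.17 in stromal-like cells alone). The remaining 11 of 23 lists stayed within the range of random lists. Under other settings the direction turned for cell cycle genes (0.18) with cells thinned to 1 depth, Alpl, Ibsp, Postn, Ccn1, Ccn2 and Nt5e in stromal-like cells alone and Mepe with no doublets removed. It turned as well for Piezo1 and Vegfa without subclusters 5, 10 and 15 and Ap5b1 and C1qc with the stricter cell filter.

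The third comparison set fullerene against diamond architecture, with 1568 and 928 mesenchymal cells behind the comparison. Medians of cartilage genes, YAP and TAZ targets, BMP and TGF-beta pathway genes, immediate early genes and glycolysis and hypoxia genes were higher in FL, and those of cell cycle and foreign body genes in DM, while most members of each list lay within 1.5-fold. In the chondrogenic list 7 of 18 members were higher in FL and 0 in DM (median 0.41, percentile 100, 0.91 stromal-like alone), although the chondrocyte-like share was larger in DM. Col10a1 (5.09-fold, 4.79 to 5.42, outside 3.22) and Col9a3 (2.16-fold, 2.03 to 2.29, outside 5.23) led it. For YAP and TAZ target genes 4 of 21 members were higher in FL and 1 in DM (median 0.27, percentile 100, 0.22 stromal-like alone). Leading it were Ccn1 (2.17-fold, 2.08 to 2.26, outside 0.801) and Amotl2 (1.70-fold, 1.62 to 1.78, outside 1.04), a matricellular protein and an angiomotin. For mechanosensing and focal adhesion genes 2 of 29 members were higher in FL and 0 in DM (median 0.13, percentile 99.4, 0.11 stromal-like alone). Examples were the stretch-gated channel Piezo2 (2.02-fold, 1.57 to 2.60, outside 0.539) and the co-activator Yap1 (1.61-fold, 1.43 to 1.81, outside 0.805). For BMP and TGF-beta genes 6 of 28 members were higher in FL and 1 in DM (median 0.24, percentile 100, 0.22 stromal-like alone). Higher in FL stood Id2 (1.80-fold, 1.72 to 1.88, outside 1.26) and Bmp4 (2.10-fold, 1.53 to 2.93, outside 0.697), and in DM Bmp2 (1.58-fold, 1.52 to 1.63, outside 1.63). For immediate early and dissociation genes 6 of 20 members were higher in FL and 0 in DM (median 0.25, percentile 100, 0.24 stromal-like alone). For glycolysis and hypoxia genes 7 of 23 members were higher in FL and 0 in DM (median 0.30, percentile 100, 0.01 stromal-like alone). Examples were Egln3 (2.00-fold, 1.80 to 2.23, outside 2.26) and Slc2a1 (1.73-fold, 1.64 to 1.83, outside 2.42), the latter a glucose transporter. Osteoblast maturation genes had a small median of 0.16 (percentile 98.6, 0.17 in stromal-like cells alone).

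Genes ranked highest in FL over DM were Bglap (37.5-fold, 32.5 to 43.5, outside 3.30), Nkain2 (53.7-fold, 20.8 to 198, outside 1.19) and Acta1 (44.3-fold, 7.65 to 1778, 2 and 1 UMIs outside), then Tac1 (26.2-fold, 6.99 to 221, outside 3.26) and Il17b (10.4-fold, 6.79 to 16.6, 2 and 2 UMIs outside). Ranked highest in DM were Gpha2 (30.7-fold, 10.1 to 153, 0 and 0 UMIs outside), Mapk12 (18.6-fold, 6.88 to 70.8, outside 4.21) and Tlcd2 (16.3-fold, 5.95 to 62.1, outside 2.16), then Ap1m2 (12.2-fold, 5.58 to 31.6, outside 7.01 with interval 2.14 to 36.3) and Msmp (12.2-fold, 5.25 to 34.7, 1 and 0 UMIs outside). A single cell held over 50% of the UMIs in the higher library for Bglap, Acta1, Gpha2, Mapk12, Tlcd2, Ap1m2 and Msmp. Fibrillar collagen and matrix genes had a median of 0.12 (percentile 99.8, 0.02 stromal-like alone). For foreign body and fibrosis genes 2 of 15 members were higher in DM and 0 in FL (median -0.22, percentile 0.16, -0.19 stromal-like alone). For angiogenesis genes 5 of 16 members were higher in FL and 3 in DM (median 0.25, percentile 99.6, -0.10 stromal-like alone). For cell cycle genes 8 of 27 members were higher in DM and 0 in FL (median -0.29, percentile 0, 0.19 stromal-like alone). For MHC class II genes 5 of 5 members were higher in DM and 0 in FL (median -1.06, percentile 0, 0.20 without subclusters 10 and 15). Nuclear genes of oxidative phosphorylation had a median of -0.13 (percentile 0.76) and haemoglobin genes one of 0.69 (percentile 99.1). The other 10 of 24 lists lay within the range of random lists. Under other settings the direction turned for osteoblast maturation genes (-0.028), Col1a1 and Bglap with no doublets removed, angiogenesis genes (-0.30) with genes counted from 10 UMIs and MHC class II genes (0.14) and Col1a1 without subclusters 5, 10 and 15. It turned as well for Runx2, Dmp1, Postn, Tnfrsf11b, Ap1m2 and Egln3 in stromal-like cells alone and Acta1 with cells thinned to 1 depth.

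Bone genes named beforehand had these levels in CPM of the mesenchymal class. Runx2, the transcription factor that starts the osteoblast programme, stood at 251 (233 to 269.6) in GP, 142 (137 to 147) in FL and 128 (122 to 133) in DM, against 66.8, 82.6 and 78.5 outside the class. Alpl, the phosphatase of mineralising cells, stood at 193 (177 to 209) in GP, 302 (295 to 309.7) in FL and 234 (226 to 241) in DM. Col1a1 differed little, with 26652 in GP, 32921 in FL and 31921 in DM. The bone sialoprotein gene Ibsp had 958 (923 to 995) in GP, 1864 (1846 to 1882) in FL and 2256 (2232 to 2279) in DM, and Spp1 had 519 (493 to 546) in GP, 3731 (3706 to 3757) in FL and 7599 (7556 to 7641) in DM. Bglap had 378 (356 to 401) in GP, 437 (428 to 445) in FL and 11.6 (10.0 to 13.4) in DM, but 1 cell held 97.1% of its UMIs in GP and 62.2% in FL, and barcodes removed as doublets held 19770 of the 20908 Bglap UMIs of the DM library. The osteocyte gene Dmp1 had 1.72 (0.559 to 4.02) in GP, 24.3 (22.3 to 26.4) in FL and 33.5 (30.8 to 36.5) in DM, its GP level resting on 5 UMIs while removed barcodes held 18 and 23 of the 53 UMIs of that library, as doublets and by the filters. Mepe had 0 UMIs in GP (up to 1.03 CPM at 3 UMIs), 5.96 (4.98 to 7.07) CPM in FL and 6.22 (5.07 to 7.56) in DM. Sp7, downstream of Runx2, had 1, 20 and 5 UMIs in GP, FL and DM. Sost and Tnfsf11, which encode sclerostin and RANKL, had 0 UMIs in this class in all 3 libraries, and at most 0.0356 CPM outside it. If the matrices count them, this allows up to 1.03, 0.136 and 0.185 CPM. The RANKL decoy Tnfrsf11b had 20.7 (15.8 to 26.6) in GP, 165 (159.5 to 170.3) in FL and 213 (206 to 219.7) in DM. Postn had 1012 (976 to 1049) in GP, 783 (772 to 795) in FL and 691 (678 to 704) in DM. The mechanically responsive genes Ccn1 and Ccn2 had 239 (222 to 257) in GP, 396 (387 to 404) in FL and 182 (176 to 189) in DM, and 1302 (1261 to 1344) in GP, 2209.7 (2190.1 to 2229) in FL and 1873 (1852 to 1894) in DM. Piezo1 was nearly level at 161 (147 to 176) in GP, 150.2 (145 to 155) in FL and 143 (137 to 149) in DM. Vegfa had 291 (272 to 312) in GP, 363 (356 to 372) in FL and 226 (218 to 233) in DM. Outside the class Alpl stood at 9.05, 10.4 and 7.38 CPM.

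**Figure D2:**
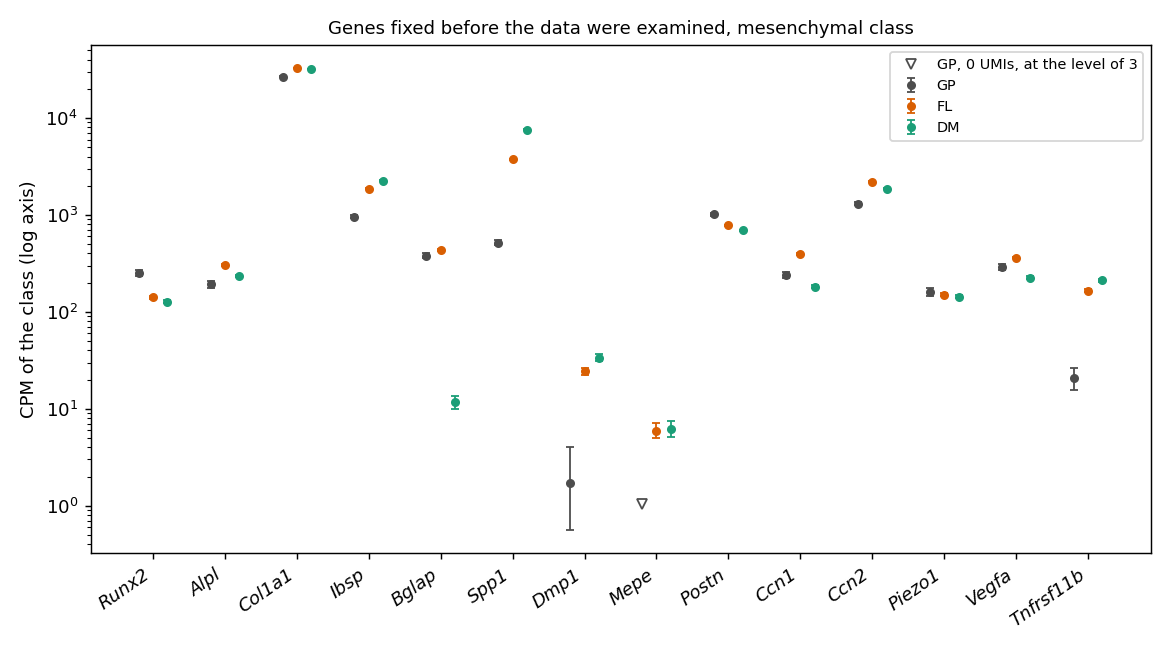
CPM of the mesenchymal class (log axis) for 14 bone genes named beforehand in GP, FL and DM, with points for the level and whiskers for the exact 95% Poisson interval, and an open triangle at the level of 3 UMIs where no UMI was seen. Spp1 ranges from 519 in GP to 7599 in DM, while Col1a1 stays between 26652 and 32921.

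Monocytes and macrophages clear debris and give rise to osteoclasts, and their make-up differed among the scaffolds. Macrophage-like cells of cluster 15 formed 13.9% (10.6 to 17.9) in GP, 52.3% (47.9 to 56.7) in FL and 65.6% (60.7 to 70.2) in DM of the class, and monocyte-like cells of cluster 14 the rest. By medians over the class, inflammatory genes were higher in GP, MHC class II and phagolysosome genes lower in GP, and osteoclast and interferon genes higher in DM, and several of these turned within its clusters. The median of all measured genes in this class lay at a log2 ratio of -0.30 for GP over FL and -0.26 for GP over DM, so medians are also given relative to it. Between GP and FL, in the inflammatory macrophage list 10 of 20 members were higher in GP and 2 in FL (median 0.40, percentile 100, 0.69 relative to the shift, 0.37 macrophage-like alone). Il6 (5.34-fold, 4.80 to 5.95, outside 0.396), Il1a (3.58-fold, 3.14 to 4.10, outside 0.758) and Ptgs2 (2.78-fold, 2.69 to 2.87, outside 0.558), cytokine and prostaglandin synthesis genes, were higher in GP. For MHC class II genes 6 of 6 members were higher in FL and 0 in GP (median -1.35, percentile 0, -1.06 relative to the shift, -0.35 macrophage-like alone). Examples were RT1-Db1 (3.10-fold, 2.94 to 3.26, outside 0.766) and RT1-Da (2.94-fold, 2.81 to 3.07, outside 0.868). For phagolysosome and lipid handling genes 8 of 19 members were higher in FL and 1 in GP (median -0.41, percentile 0.13, -0.12 relative to the shift, -0.04 macrophage-like alone). It was led by the cysteine protease Ctss (3.06-fold, 2.62 to 3.58, outside 0.804). Unfolded protein response genes had a median of 0.36 (percentile 99.9, 0.18 macrophage-like alone), and metal and iron handling genes one of 0.16 (percentile 98.8, 0.26). For immediate early genes 6 of 20 members were higher in GP and 4 in FL (median 0.26, percentile 99.7, 0.56 relative to the shift, -0.03 macrophage-like alone). Oxidative phosphorylation genes had a median of -0.38 (-0.09 relative to the shift). The other 6 of 13 lists lay within the range of random lists, among them osteoclast differentiation and resorption, with a median of -0.09 over the class, 0.79 in macrophage-like cells alone (-0.21 without their top cells) and -0.79 without the 5 cells per library richest in the list.

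Between GP and DM the osteoclast differentiation and resorption list differed most in the mono-macrophage class, where 11 of 17 members were higher in DM and 1 in GP (median -1.31, percentile 0, -1.05 relative to the shift, 0.20 macrophage-like alone, -0.66 monocyte-like alone). Nfatc1 (4.55-fold, 3.67 to 5.69, outside 1.58), Ctsk (3.05-fold, 2.88 to 3.23, outside 3.55) and Acp5 (2.84-fold, 2.69 to 2.99, outside 0.931), the master regulator, the collagen-cleaving protease and the acid phosphatase of osteoclasts, were higher in DM over the class. Without the top cell of each library Ctsk was 13.8-fold and Acp5 9.05-fold higher in DM. The macrophage-like median rests on 51 cells of GP, of which 1 held 70.4% of the list's UMIs, and was -0.81 without the top cell of each library. For interferon response genes 13 of 18 members were higher in DM and 0 in GP (median -1.10, percentile 0, -0.84 relative to the shift, -0.47 macrophage-like alone). Leading it were Oasl2 (4.49-fold, 3.28 to 6.25, outside 1.40) and Isg15 (3.15-fold, 2.54 to 3.93, outside 2.07). For foreign body and fibrosis genes 9 of 12 members were higher in DM and 0 in GP (median -1.10, percentile 0, -0.84 relative to the shift, -0.09 macrophage-like alone). It was led by the tetraspanin Cd9 (3.94-fold, 3.71 to 4.17, outside 4.81). For phagolysosome and lipid handling genes 12 of 19 members were higher in DM and 1 in GP (median -0.78, percentile 0, -0.52 relative to the shift, 0.28 macrophage-like alone), and for MHC class II genes 5 of 6 members were higher in DM and 0 in GP (median -0.84, percentile 0.61, -0.58 relative to the shift, 0.63 macrophage-like alone, 0.90 monocyte-like alone), so both had the opposite direction in macrophage-like cells alone. In the inflammatory list 9 of 20 members were higher in GP and 4 in DM (median 0.36, percentile 99.9, 0.62 relative to the shift, -0.07 macrophage-like alone). Higher in GP stood Il6 (4.77-fold, 4.29 to 5.30, outside 0.532) and Ccl2 (3.13-fold, 3.09 to 3.18, outside 0.560). Unfolded protein response genes had a median of 0.33 (percentile 99.5, 0.15 in macrophage-like cells alone). Metal and iron handling genes had a median of 0.23 (percentile 98.2, 0.06 in macrophage-like cells alone), and oxidative phosphorylation genes one of -0.52 (percentile 0.17, 0.06 macrophage-like alone). The other 4 lists lay within the range of random lists.

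Between FL and DM, where the median of all genes lay at 0.01, osteoclast genes were again higher in DM in the mono-macrophage class, and here the direction held in macrophage-like cells but was smaller without the 5 cells per library richest in the list (median -0.42). In the list 12 of 17 members were higher in DM and 1 in FL (median -0.9996, percentile 0, -0.64 macrophage-like alone, -0.19 monocyte-like alone). Leading it were Mmp9 (10.3-fold, 8.14 to 13.2, outside 0.759), Ctsk (8.28-fold, 7.64 to 8.98, outside 0.668) and Acp5 (3.30-fold, 3.13 to 3.47, outside 1.33). For interferon response genes 10 of 19 members were higher in DM and 0 in FL (median -0.66, percentile 0, -0.33 macrophage-like alone). Leading it were Oasl (2.16-fold, 2.04 to 2.28, outside 1.47) and Isg15 (2.14-fold, 1.80 to 2.54, outside 0.862). For MHC class II genes 5 of 7 members were higher in FL and 0 in DM (median 0.60, percentile 100, 1.04 macrophage-like alone). Alternatively activated macrophage genes had a median of 0.25 (percentile 99.1, 0.63 macrophage-like alone). In the inflammatory list 3 of 20 members were higher in DM and 0 in FL (median -0.19, percentile 0.48, -0.31 macrophage-like alone). For glycolysis and hypoxia genes 7 of 22 members were higher in FL and 0 in DM (median 0.37, percentile 100, 0.00 macrophage-like alone). Leading it were Ankrd37 (5.31-fold, 4.09 to 6.97, outside 2.63) and Egln3 (4.60-fold, 3.88 to 5.49, outside 1.82). Immediate early genes had a median of -0.31 (-0.20 in macrophage-like cells alone), metal and iron handling genes -0.22 (-0.33), foreign body genes -0.29 (-0.07), cell cycle genes 0.21 (-0.02) and oxidative phosphorylation genes -0.10 (-0.03). The other 2 lists, phagolysosome and lipid handling and unfolded protein response, lay within the range of random lists.

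In the mono-macrophage class the ranked genes higher in GP than in FL were Ccl20 (96.8-fold, 16.9 to 3873, outside 0.188), Gucy1b2 (45.7-fold, 15.2 to 225, outside 2.38) and Rln1 (80.5-fold, 13.9 to 3228, outside 1.12), and those higher in GP than in DM Retn (121-fold, 21.2 to 4822, outside 8.28), Gucy1b2 (31.4-fold, 11.9 to 117, outside 0.932) and Rln1 (24.6-fold, 8.04 to 122, outside 3.98). Higher in FL than in GP were Col2a1 (at least 39.0-fold, outside 6819.6), Mustn1 (at least 27.8-fold, outside 9.56) and Mgp (29.3-fold, 15.8 to 61.7, outside 12.0), and higher in DM than in GP Col2a1 (at least 25.2-fold, outside 4691), Mgp (25.0-fold, 13.4 to 52.7, outside 9.99) and Ibsp (33.9-fold, 11.3 to 167, outside 11.7). Col2a1, Mgp and Ibsp are matrix genes of cartilage and bone whose ratios were also large outside the class. Higher in FL than in DM were Elane (10.8-fold, 6.46 to 19.2, outside 1.31), Bglap (6.63-fold, 4.60 to 9.86, outside 17.2) and Mustn1 (7.40-fold, 4.14 to 14.4, outside 0.915), and higher in DM than in FL Ccl20 (233-fold, 41.3 to 9227, outside 0.579), Slc17a2 (56.8-fold, 15.3 to 475, outside 1.58) and Ccdc154 (44.4-fold, 14.8 to 218, outside 1.36). A single cell held over 50% of the UMIs in the higher library for Ccdc154, Ccl20, Elane, Mustn1 and Rln1. Of the genes named beforehand, Il1b, a gene that also leads the monocyte-like cluster, had 4625 (4565 to 4686) in GP, 1721 (1688 to 1754) in FL and 2079 (2041 to 2117) in DM, in CPM. Acp5 had 367 (350.2 to 384) in GP, 316 (302 to 330.3) in FL and 1041 (1015 to 1068) in DM, and Ctsk 301 (286 to 317) in GP, 111 (103 to 119.5) in FL and 918 (893 to 943) in DM, with 1 cell holding 75.4% of the Acp5 and 85.7% of the Ctsk UMIs in GP. Mrc1, a mannose receptor of resident macrophages, had 26.7 (22.3 to 31.7) in GP, 112 (104 to 121) in FL and 83.2 (75.9 to 91.1) in DM. Arg1 had 49.1 (43.0 to 55.7) in GP, 48.5 (43.1 to 54.3) in FL and 31.7 (27.2 to 36.7) in DM, and Spp1 1079 (1049.6 to 1108) in GP, 1784 (1750.2 to 1817) in FL and 3134 (3088 to 3181) in DM. The scavenger receptor gene Cd163 had 12, 16 and 2 UMIs, and Tnf had 0 in this class and outside it in each library, so whether these matrices count Tnf is open and no limit is given. Directions turned for MHC class II genes (0.90, GP over DM), alternatively activated macrophage genes (-0.12, FL over DM), oxidative phosphorylation genes (0.14, FL over DM), metal and iron handling genes (0.17, FL over DM), Acp5, Mrc1, Arg1, Slc17a2 and Mmp9 in monocyte-like cells alone, Acp5, Ctsk and Mmp9 with the stricter cell filter, Acp5 with each cell weighted alike and Acp5 with cells thinned to 1 depth. They turned as well for Acp5 and Ctsk without the top cell of each gene, Acp5, Ctsk, Il1b, Mrc1, Ccl2, Egln3 and Il6 in macrophage-like cells alone and Rln1 with no doublets removed.

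More neutrophil-like cells were immature in GP. Medians of mature neutrophil, interferon response and immediate early genes were lower in GP over the class, and in the immature cluster alone these GP over FL medians turned. The immature cluster 5, led by granule genes, formed 81.8% (78.4 to 84.8) in GP, 52.6% (48.4 to 56.7) in FL and 52.3% (46.9 to 57.6) in DM of the class, and the mature cluster 7 the rest. The median of all genes lay at 0.27 for GP over FL, 0.25 for GP over DM and -0.02 for FL over DM. Between GP and FL, in the mature and activated neutrophil list 10 of 17 members were higher in FL and 1 in GP (median -0.82, percentile 0, -1.09 relative to the shift, 0.15 cluster 5 alone, -0.11 cluster 7 alone). Cxcl2 (3.43-fold, 3.38 to 3.48, outside 0.710) and Nlrp3 (3.55-fold, 2.91 to 4.36, outside 0.447), a chemokine and an inflammasome sensor, led it in FL. For interferon response genes 6 of 11 members were higher in FL and 0 in GP (median -0.84, percentile 0.01, -1.11 relative to the shift, 0.19 cluster 5 alone, -0.85 cluster 7 alone). Examples were Isg15 (4.74-fold, 3.47 to 6.60, outside 1.88) and Irf7 (3.88-fold, 2.56 to 6.04, outside 1.27). For immediate early genes 9 of 19 members were higher in FL and 0 in GP (median -0.57, percentile 0.01, -0.84 relative to the shift, 0.07 cluster 5 alone, -0.04 cluster 7 alone), and for glycolysis and hypoxia genes 10 of 19 members were higher in FL and 0 in GP (median -0.63, percentile 0, -0.90 relative to the shift, -0.44 cluster 5 alone, -0.27 cluster 7 alone). An example was the glucose transporter Slc2a1 (5.27-fold, 4.46 to 6.25, outside 2.06). Primary granule genes had a median of -0.38 (-0.65 relative to the shift, -0.71 in cluster 5 alone). Metal and iron handling genes had one of -0.26 (0.54 in cluster 5 alone). The other 5 of 11 lists, secondary and tertiary granule genes among them (0.13), lay within the range of random lists.

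Between GP and DM, neutrophil-like cells gave the following lists outside the range of random lists. In the mature and activated list 13 of 17 members were higher in DM and 0 in GP (median -0.90, percentile 0, -1.15 relative to the shift, -0.26 cluster 5 alone, 0.02 cluster 7 alone). Leading it were Cxcl2 (2.75-fold, 2.71 to 2.80, outside 0.709) and Il1r2 (2.90-fold, 2.52 to 3.35, outside 0.762). For interferon response genes 7 of 10 members were higher in DM and 2 in GP (median -1.24, percentile 0, -1.49 relative to the shift, -0.66 cluster 5 alone, -0.26 cluster 7 alone). For immediate early genes 15 of 19 members were higher in DM and 0 in GP (median -1.11, percentile 0, -1.36 relative to the shift, -0.71 cluster 5 alone, -0.34 cluster 7 alone). Leading it were Egr1 (9.17-fold, 8.36 to 10.1, outside 2.78) and Dnajb1 (5.73-fold, 5.400 to 6.08, outside 2.29). Glycolysis and hypoxia genes had a median of -0.33 (-0.18 in cluster 5 and 0.19 in cluster 7), and metal and iron handling genes -0.20 (0.31 and 0.13). The other 6 lists stayed inside. Between FL and DM, 10 of 19 members were higher in DM and 0 in FL (median -0.64, percentile 0, -0.83 cluster 5 alone, -0.19 cluster 7 alone) for immediate early genes. Primary granule genes were higher in FL, where 4 of 6 members were higher in FL and 0 in DM (median 0.89, percentile 100, 0.81 cluster 5 alone). Examples were Elane (2.21-fold, 1.70 to 2.90, outside 1.33) and Mpo (1.55-fold, 1.36 to 1.77, outside 1.33). Glycolysis and hypoxia genes had a median of 0.27 (percentile 100), and MHC class II genes one of -0.52 (percentile 1.38). The other 7 lists lay inside the range.

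Ranked genes of the neutrophil class were, for GP over FL, Ac1576 (62.8-fold, 17.1 to 523, outside 1.5), Otof (25.8-fold, 6.84 to 218, outside 0.331) and Olfm4 (5.63-fold, 5.25 to 6.04, outside 6.43), of which Olfm4 leads the immature cluster. For GP over DM they were Retn (3.70-fold, 3.16 to 4.34, outside 12.6), Ac1576 (5.49-fold, 3.11 to 10.6, outside 1.03) and Ddc (8.96-fold, 2.91 to 44.8, outside 1.15), Retn being the gene of resistin. For FL over GP they were Col2a1 (at least 55.8-fold, outside 6583), Comp (at least 45.3-fold, outside 135) and Hapln1 (at least 26.4-fold, outside 763), and for DM over GP Col2a1 (at least 44.3-fold, outside 4449), Fn1 (31.9-fold, 19.2 to 56.6, outside 10.1) and Col11a1 (33.8-fold, 12.6 to 128, outside 14.0), matrix genes that do not belong to neutrophils. For FL over DM they were Bglap (4.16-fold, 2.73 to 6.60, outside 17.4), Ctsg (3.53-fold, 2.63 to 4.81, outside 1.41) and Siglec5 (5.21-fold, 2.25 to 14.8, outside 0.533), and for DM over FL Ccl5 (29.3-fold, 13.01 to 81.8, outside 1.04), Ubqln1 (6.22-fold, 4.69 to 8.34, outside 1.29) and Cecr2 (4.78-fold, 3.42 to 6.77, outside 1.82). A single cell held over 50% of the UMIs in the higher library for Ac1576, Ccl5 and Otof. Directions turned for primary granule genes (0.13, GP over FL) and metal and iron handling genes (0.010, GP over DM) with the looser cell filter, primary granule genes (0.096, GP over FL), metal and iron handling genes (0.15, GP over FL), metal and iron handling genes (0.0026, GP over DM), primary granule genes (-0.058, FL over DM), Ctsg and Elane with the stricter cell filter and primary granule genes (0.22, GP over FL) and MHC class II genes (0.26, FL over DM) with no doublets removed. They turned as well for primary granule genes (0.098, GP over FL) with cells thinned to 1 depth, Ddc, Cxcl2, Il1r2 and Mpo in cluster 7 alone and Nlrp3 in cluster 5 alone.

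Endothelial-like cells of cluster 11 numbered 44 in GP, 135 in FL and 210 in DM. Medians of angiogenesis, interferon response and glycolysis and hypoxia genes were lower in GP than in both other libraries. For angiogenesis genes between GP and FL 4 of 15 members were higher in FL and 1 in GP (median -0.40, percentile 0.245). Examples were Kdr (2.38-fold, 1.69 to 3.44, outside 1.35) and Dll4 (2.82-fold, 1.35 to 6.80, outside 1.10), a VEGF receptor and a Notch ligand of sprouting vessels. Between GP and DM 7 of 18 members were higher in DM and 0 in GP (median -0.49, percentile 0.03). Examples were Apln (9.66-fold, 2.62 to 80.8, outside 5.36) and Dll4 (2.27-fold, 1.11 to 5.39, outside 1.57). Interferon response genes had medians of -0.90 and -1.26 for GP over FL and GP over DM. Glycolysis and hypoxia genes had medians of -0.82, -0.54 and 0.44 for GP over FL, GP over DM and FL over DM, led by lactate dehydrogenase, Ldha (2.81-fold, 2.22 to 3.59, outside 1.68). Immediate early genes had medians of -0.69 for GP over FL and 0.29 for FL over DM. Oxidative phosphorylation genes were highest in DM, with medians of -0.57 for GP over DM and -0.35 for FL over DM. Cell cycle genes gave -0.56 for GP over FL and 0.57 for FL over DM, though a single cell held 90.5% of the Top2a UMIs in FL. For FL over DM, metal and iron handling genes had a median of 0.32 and unfolded protein response genes one of -0.23. YAP and TAZ target genes and mechanosensing genes lay within the range of random lists in all 3 pairs of this class.

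Ranked genes of the endothelial class higher in GP than in FL were Col8a1 (7.32-fold, 4.66 to 11.8, outside 0.131), Hist1h2bo (4.39-fold, 2.95 to 6.59, outside 2.27) and Bpgm (3.76-fold, 2.78 to 5.09, outside 0.530), and those higher in GP than in DM Robo1 (7.48-fold, 5.27 to 10.7, outside 0.507), Jade3 (6.22-fold, 3.54 to 10.97, outside 1.12) and Ank2 (4.35-fold, 3.26 to 5.78, outside 2.46). Higher in FL than in GP were Depp1 (9.54-fold, 6.46 to 14.7, outside 3114 with interval 558 to 123013), Tll1 (9.14-fold, 6.42 to 13.4, outside 1.75) and Igfbp5 (14.1-fold, 6.39 to 38.8, outside 8.66), and higher in DM than in GP Mmp3 (at least 5.67-fold, outside 3.74), Igfbp5 (8.47-fold, 3.85 to 23.3, outside 6.17) and Tll1 (5.02-fold, 3.53 to 7.38, outside 1.43). Higher in FL than in DM were Cryab (53.8-fold, 20.4 to 201, outside 2.14), Rgs5 (15.8-fold, 8.42 to 32.9, outside 0.520) and Rrad (12.8-fold, 6.03 to 31.3, outside 1.19), of which Rgs5 also leads the pericyte-like cluster. Higher in DM than in FL were Mmp3 (9.95-fold, 4.13 to 31.3, outside 1.06), Tppp3 (4.35-fold, 3.04 to 6.39, outside 2.33) and Apln (4.72-fold, 2.60 to 9.39, outside 0.393), Apln being the ligand made by sprouting endothelial tip cells. A single cell held over 50% of the UMIs in the higher library for Cryab, Mmp3, Robo1 and Rrad. With 44 cells in GP, single cells carry much of each ratio against that library. Directions turned for cell cycle genes (0.37, GP over FL), cell cycle genes (-0.20, FL over DM) and Top2a with each cell weighted alike and cell cycle genes (-0.11, FL over DM) and Mmp3 with cells thinned to 1 depth. They turned as well for cell cycle genes (0.090, GP over FL) with genes counted from 10 UMIs and Top2a without the top cell of each gene.

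Some lists moved in several classes at once. Glycolysis and hypoxia genes had medians outside the range of random lists and higher in FL than in DM in 6 of 6 classes, higher in FL than in GP in 5 and higher in DM than in GP in 4. The FL over DM median nevertheless came to 0.01 in stromal-like and 0.00 in macrophage-like cells alone. Interferon response genes were higher than in GP in 4 of 6 classes of FL and in 5 of DM. Dendritic cell-like GP over FL medians, not counted, were 0.62 for these, 0.78 for immediate early and -0.95 for glycolysis genes. In B-lineage cells, glycolysis and hypoxia medians were -0.79, -0.29 and 0.45 for GP over FL, GP over DM and FL over DM, with P4ha1 (3.13-fold, 2.81 to 3.48, outside 3.58) and Pdk1 (2.87-fold, 2.13 to 3.87, outside 1.600) as examples. Immediate early medians in these cells were -0.43, -0.78 and -0.25, led by Atf3 (4.70-fold, 4.16 to 5.32, outside 3.60) and Ier3 (3.64-fold, 3.19 to 4.15, outside 1.66), and interferon medians were -0.47, -0.51 and -0.11. MHC class II medians were -0.57, -0.13 and 0.75. In T cell-like and NK cell-like cells, where the median of all genes lay at 0.13 for FL over DM, immediate early medians were -0.65 and -0.99 for GP over FL and GP over DM, and glycolysis medians -0.85 and -0.04. The time from dissection to droplets, which can raise immediate early genes, was not stated for any library.

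**Figure D3:**
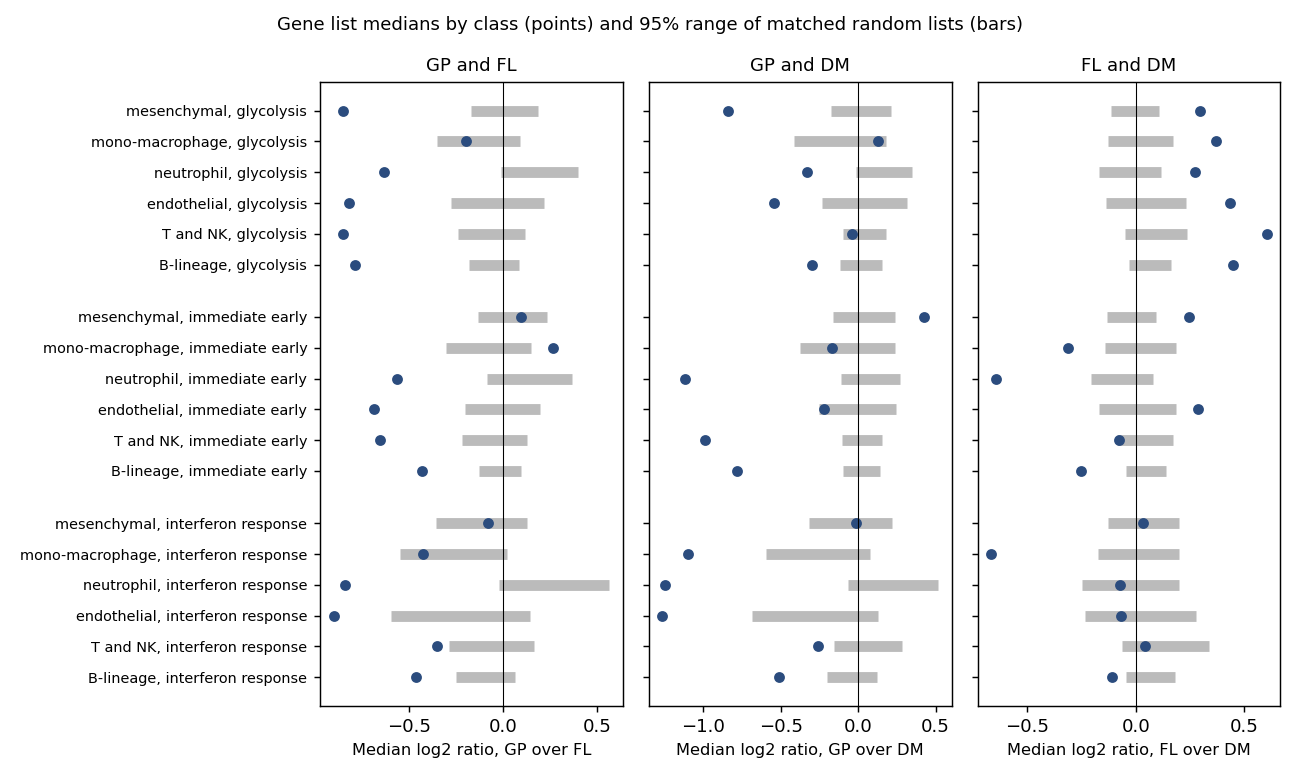
Median log2 ratio (horizontal axis) of the glycolysis and hypoxia, immediate early and interferon lists in 6 cell classes for the pairs GP over FL, GP over DM and FL over DM, with points for the median of the list and grey bars for the 95% range of random lists matched on expression. In B-lineage cells the glycolysis and hypoxia median is -0.79 for GP over FL and 0.45 for FL over DM.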

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

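The test of osteoclast genes in macrophage-like cells alone was set before its result was seen, and the other tests of this part were chosen after. Barcodes left out as doublets or by the filters held UMIs of genes named beforehand. Bglap had 3571 UMIs in barcodes marked as doublets in GP and 19770 in DM, and 19430 of the latter lay in 1 barcode of 130982 UMIs. Cd163 had 41 UMIs in barcodes of GP that failed the filters. No control library existed. These were at least 56.6% of a gene's UMIs in a library, and other genes passed the limit a count of 0 allows.

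Chondrocyte-like cells made up a far smaller part of the mesenchymal class in GP than in FL and DM. Removal of cells as the whole cause is argued against, since Col2a1 in CPM over all barcodes, removed ones included, was 153-fold lower in GP than in the nearer library. The size of the Col2a1 ratio is less firm, as 1 barcode marked as a doublet held 277 of the 291 Col2a1 UMIs of GP, and with no cells removed as doublets the FL over GP ratio was 35.2 in place of 8909. Scaffold architecture, the place and amount of tissue dissected and animal-to-animal variation stay open and were not tested, and with 1 library each they may all contribute.

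Bglap was 37.5-fold higher in FL than in DM within mesenchymal cells. With no cells removed as doublets the ratio was 0.384, which follows from the barcode of DM named above, so the direction hinges on it. Among the kept cells FL stayed 15.8-fold higher without the top cell of each library. No explanation was tested, and whether that barcode held 1 osteoblast, a clump of cells or mineral debris stays open.

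Osteoclast genes had a median log2 ratio of -1.31 for GP over DM in the mono-macrophage class. In monocyte-like cells it was -0.66 (all genes -0.20 without the top cells). For 9 members this weakly argues against DM's larger macrophage-like part as whole cause. In macrophage-like cells alone it was 0.20, the outcome that part predicts under the rule set beforehand, but in a later check 1 of 51 such cells of GP held 70.4% of the list's UMIs, and without the top cell of each library the median was -0.81, and -0.30 without 5, so it is undecided there. Over the class, the 5 richest cells per library held 53.4% of the list's UMIs in GP, 20.8% in FL and 48.8% in DM. The median without them was -1.27, but class make-up still differs there, so a handful of osteoclast-like carriers stays undecided. Without those cells GP over FL was -0.79 and FL over DM -0.42. An effect of architecture stays open and was not tested.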

How the results depend on the processing

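The settings that take single clusters alone, leave out subclusters or top cells, or count shares outside the B-lineage were chosen after the data were seen, and the others before. No paired analysis was possible because each scaffold had 1 library and no sample was matched to another. Over 482 values and 4565 values under alternatives, 3351 stayed within the interval or random range of the reported value, 1088 left it without turning a called direction, and 126 turned in direction, spread over 94 results. The mesenchymal share ran from 2.30 to 8.02% in GP, 23.4 to 43.0% in FL and 12.8 to 34.6% in DM, the upper ends being shares outside the B-lineage. Osteoclast genes of the mono-macrophage class kept their FL over DM direction in all 10 settings run, but with medians from -1.16 to -0.19. The GP over DM median turned in macrophage-like cells alone, where 1 cell of GP carried it. Thinning left out 928 cells in GP, 714 in FL and 800 in DM that were too shallow. Some alternatives gave no value. The erythroid cell-like share was missing under the stricter filter and at a resolution of 0.5, the osteoblast-like subcluster under the stricter filter, and lists with too few measured members, such as haemoglobin or MHC class II genes, under thinning or a minimum of 200 UMIs. Leaving free RNA genes out of the totals gave no value for the granule genes it removes. The few mesenchymal and endothelial cells of GP limit the ratios against it in those classes.

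Values that turned, and main results that moved, follow by setting, with the pair in parentheses and list medians on the log2 scale. Leaving out a top cell or a cluster shows by its construction that the value rested on it, and for the other settings the cause was not tested. With the looser cell filter, the B-lineage share was 60.0% in DM, the mesenchymal share was 23.4% in FL and the chondrocyte-like part of mesenchymal cells was 24.8% in FL. The gene ratio of mesenchymal cells was 3.64 for Bglap (GP over FL). List medians of neutrophil cells were 0.13 for neutrophil primary granule (GP over FL) and 0.010 for metal and iron handling (GP over DM). With the stricter cell filter, the B-lineage share was 67.1% in GP and 57.1% in DM, the mesenchymal share was 27.4% in FL and 16.3% in DM and the chondrocyte-like part of mesenchymal cells was 22.9% in FL and 37.3% in DM. The list median of mesenchymal cells was -0.80 for osteoblast maturation (GP over FL). Gene ratios of mesenchymal cells were 0.729 for C1qc, 0.535 for Ap5b1 and 0.309 for Cd2 (GP over FL) and 0.866 for Ap5b1 and 0.825 for C1qc (GP over DM). List medians of the mono-macrophage class were -0.69 for osteoclast genes (GP over FL), -0.66 for osteoclast genes (GP over DM) and -0.20 for osteoclast genes (FL over DM). Gene ratios of the mono-macrophage class were 0.336 for Acp5 and 0.803 for Ctsk (GP over FL) and 0.365 for Mmp9 (DM over FL). List medians of neutrophil cells were 0.096 for neutrophil primary granule and 0.15 for metal and iron handling (GP over FL), 0.0026 for metal and iron handling (GP over DM) and -0.058 for neutrophil primary granule (FL over DM). Gene ratios of neutrophil cells were 0.876 for Ctsg and 0.807 for Elane (FL over DM). With no cells removed as doublets, the B-lineage share was 39.9% in FL and the chondrocyte-like part of mesenchymal cells was 19.6% in FL. The list median of mesenchymal cells was -0.028 for osteoblast maturation (FL over DM). Gene ratios of mesenchymal cells were 0.978 for Col1a1 and 0.384 for Bglap (FL over DM), 3.28 for Bglap and 1.41 for Mepe (GP over FL) and 1.38 for Mepe (GP over DM). Gene ratios of the mono-macrophage class were 0.0973 for Rln1 (GP over FL) and 0.371 for Rln1 (GP over DM). List medians of neutrophil cells were 0.22 for neutrophil primary granule (GP over FL) and 0.26 for MHC class II (FL over DM). The list median of T and NK cells was 0.043 for cell cycle (GP over FL). At a Leiden resolution of 2.0, the B-lineage share was 65.0% in GP, 39.5% in FL and 58.6% in DM. With each library clustered alone, the B-lineage share was 62.0% in GP and 55.2% in DM. As shares of cells outside the B-lineage, the mesenchymal share was 8.02% in GP, 43.0% in FL and 34.6% in DM. At a resolution of 0.5 in the second clustering, the chondrocyte-like part of mesenchymal cells was 22.8% in FL. With median of ratios scaling, the list median of the mono-macrophage class was 0.21 for osteoclast genes (GP over FL). With each cell weighted alike, the gene ratio of mesenchymal cells was 1.91 for Bglap (GP over FL). List medians of the mono-macrophage class were -0.59 for osteoclast genes (GP over FL) and -0.62 for osteoclast genes (FL over DM). The gene ratio of the mono-macrophage class was 0.607 for Acp5 (GP over FL). List medians of endothelial cells were 0.37 for cell cycle (GP over FL) and -0.20 for cell cycle (FL over DM). The gene ratio of endothelial cells was 0.716 for Top2a (FL over DM). With cells thinned to 2000 UMIs, list medians of mesenchymal cells were 0.050 for osteoblast maturation and -0.18 for osteoclast coupling signals (GP over FL) and 0.18 for cell cycle (GP over DM). Gene ratios of mesenchymal cells were 2.25 for Bglap and 1.76 for Mepe (GP over FL), 0.402 for Acta1 (FL over DM) and 0.939 for Bmp2 (FL over GP). List medians of the mono-macrophage class were -0.51 for osteoclast genes (GP over FL) and -0.48 for osteoclast genes (FL over DM). The gene ratio of the mono-macrophage class was 0.661 for Acp5 (GP over FL). The list median of neutrophil cells was 0.098 for neutrophil primary granule (GP over FL). The list median of endothelial cells was -0.11 for cell cycle (FL over DM). The gene ratio of endothelial cells was 0.455 for Mmp3 (DM over GP). With genes counted from 10 UMIs, the list median of mesenchymal cells was -0.30 for angiogenesis (FL over DM). The list median of endothelial cells was 0.090 for cell cycle (GP over FL). In stromal-like cells alone list medians were -0.086 for osteoblast maturation, -0.13 for osteoclast coupling signals and -0.00097 for haematopoietic niche factors (GP over FL), 0.28 for osteoblast maturation, 0.0086 for mineralisation, -0.045 for WNT pathway and 0.12 for cell cycle (GP over DM) and -0.10 for angiogenesis and 0.19 for cell cycle (FL over DM). In stromal-like cells alone gene ratios were 0.992 for Runx2, 6.54 for Dmp1, 0.919 for Postn, 1.03 for Tnfrsf11b and 0.632 for Egln3 (FL over DM), 1.01 for Alpl, 1.41 for Ibsp, 0.881 for Postn, 0.903 for Ccn1 and 1.07 for Ccn2 (GP over DM), 1.79 for Ibsp and 0.958 for Postn (GP over FL), 0.833 for Ap1m2 (DM over FL), 0.568 for Bmp2 and 0.849 for Trpv4 (FL over GP) and 0.956 for Nt5e (DM over GP). In macrophage-like cells alone list medians were 0.79 for osteoclast genes, -0.027 for immediate early genes and 0.069 for oxidative phosphorylation (GP over FL), -0.070 for inflammatory macrophage, 0.28 for phagolysosome and lipid handling, 0.20 for osteoclast genes, 0.63 for MHC class II and 0.061 for oxidative phosphorylation (GP over DM) and -0.64 for osteoclast genes, -0.021 for cell cycle and -0.0022 for glycolysis and hypoxia (FL over DM). In macrophage-like cells alone gene ratios were 1.33 for Acp5, 1.27 for Ctsk, 0.814 for Il1b, 1.20 for Mrc1, 0.718 for Ccl2 and 0.411 for Il6 (GP over DM), 0.835 for Egln3 (FL over DM) and 0.841 for Il6 (GP over FL). In monocyte-like cells alone, list medians were -0.66 for osteoclast genes and 0.90 for MHC class II (GP over DM) and -0.12 for alternatively activated macrophage, -0.19 for osteoclast genes, 0.14 for oxidative phosphorylation and 0.17 for metal and iron handling (FL over DM). Gene ratios were 0.722 for Acp5 (GP over FL), 0.771 for Mrc1 and 0.470 for Arg1 (FL over DM), 0.922 for Arg1 (GP over DM) and 0.692 for Slc17a2 and 0.692 for Mmp9 (DM over FL). Without subclusters 10 and 15, the list median was 0.20 for MHC class II (FL over DM). The gene ratio was 0.989 for C1qc (GP over FL). Without subclusters 5, 10 and 15, list medians were 0.0017 for fibrillar collagen and matrix (GP over FL) and 0.14 for MHC class II (FL over DM). Gene ratios were 0.999 for Col1a1 (FL over DM), 1.31 for Bglap, 0.706 for Il7 and 1.00 for Mmp3 (GP over FL) and 0.813 for Piezo1 and 0.988 for Vegfa (GP over DM). In the immature neutrophil cluster alone, list medians were 0.15 for mature and activated neutrophil, 0.19 for interferon response, 0.068 for immediate early genes and 0.54 for metal and iron handling (GP over FL) and 0.31 for metal and iron handling (GP over DM). The gene ratio was 0.436 for Nlrp3 (FL over GP). In the mature neutrophil cluster alone, list medians were 0.040 for metal and iron handling (GP over FL) and 0.023 for mature and activated neutrophil, 0.19 for glycolysis and hypoxia and 0.13 for metal and iron handling (GP over DM). Gene ratios were 0.526 for Ddc (GP over DM), 0.879 for Cxcl2 and 0.981 for Il1r2 (DM over GP) and 0.645 for Mpo (FL over DM). Without the top cell of each gene, gene ratios of mesenchymal cells were 0.977 for C1qc and 0.789 for Ap5b1 (GP over FL). Gene ratios of the mono-macrophage class were 0.346 for Acp5 and 0.690 for Ctsk (GP over FL). The gene ratio of endothelial cells was 0.482 for Top2a (FL over DM).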

Other observations

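The count of genes that rest on a single cell was chosen after the data were seen, and no explanation was tested in this part. Gene classes kept out of the ranking took different shares of all UMIs. Ribosomal protein genes held 17.3% in GP, 14.8% in FL and 15.4% in DM, mitochondrially encoded genes 4.17% in GP, 2.62% in FL and 4.42% in DM and genes without a symbol 7.71% in GP, 7.93% in FL and 7.02% in DM. Haemoglobin genes held 0.0466% in GP, 0.265% in FL and 0.0509% in DM, and immunoglobulin genes, the products of mature B-lineage cells, 0.205% in GP, 0.0810% in FL and 0.126% in DM. Of the Y-linked genes, Eif2s3y and Kdm5d had 7484 and 2781 UMIs in GP, 6858 and 1789 in FL and 6671 and 2160 in DM, while Ddx3y had 1, 0 and 2 UMIs and Usp9y 4, 9 and 0. Single cells carried many of the genes ranked by ratio. In 34 of 84 ranked genes 1 cell held over 50% of the UMIs of the higher library, 17 of 30 in the mesenchymal class, 8 of 18 in the mono-macrophage class, 5 of 18 in the endothelial class and 4 of 18 in the neutrophil class.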
